A study of Homo sapiens with 8 samples.

How the data were processed

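Total RNA of 8 HL60 samples was measured on 8 one-colour arrays: 4 labelled untreated and 4 labelled as given 10 µM DIMATE for 6 h. Per the labels' protocols, cells grew in multiwell plates, RNA was extracted with a column kit, and 100 ng of RNA was labelled with Cy3 by a low-input amplification protocol. The labels name no vehicle for the untreated samples, no analysis test and no separate cultures behind the replicates.

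Per the file headers, the deposited files are output of Agilent Feature Extraction 10.5.1.1 for array design 039494, with 62976 spots per array. The processed signal in the deposited files is an intensity on a linear scale, from which Feature Extraction had subtracted background and a spatial trend on each array, per the file headers; no scaling between arrays is recorded there. The mean and background intensities of each spot in the deposited files were used for 1 alternative. Flags for well above background, saturation and outlier spots were also taken as deposited. Positions are those printed in the files, on hg19; the files do not say which exon or UTR a probe meets.

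Of 50599 probes that are not controls, 28174 were named through the accession in the file and 2618 and 620 through a current or an older symbol of the RefSeq gene table of assembly GRCh38.p14, which was used for names only. The other 19187 keep the file's name. All groups come from the sample titles.

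Levels are log2 of the processed signal minus each array's 75th percentile over spots that are not controls. Outlier spots were left out and the spots of a probe averaged. A probe was tested if it was well above background on all 4 arrays of at least 1 group, which left 23031 probes; 132 probes lacked a value on an array because of outlier flags and were not tested. A gene with several probes is represented by the probe with the highest mean, and probes of a gene can disagree, as stated where it matters. No spot that is not a control was saturated. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (1.17.8), and p-values were adjusted by Benjamini-Hochberg over 17499 genes and transcripts. Gene lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, over 35 lists, with an estimated correlation and with fry as alternatives. Measures of array quality were compared by two-sided exact permutation tests.

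The 35 lists hold 1002 genes, 986 of them on the array, and were written from general knowledge of the pathways. The lists, the test, the alternatives and the rule for named genes were chosen before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, 3 genes in each direction known only as a bound, the 91 sentinel genes of the lists, and up to 4 further members per list by adjusted p. As 0 genes passed, its first 2 parts named none, and the text turned to sentinels and list members. It describes 67 genes; which of the genes that the rule allows were described was settled after their values were seen. After the values were seen, the 20 protein-coding genes with the widest spread over the 8 arrays were added; EGR1, FOS, FOSB, DUSP1, HSPA6, BIRC3, CCL4, CD86, NFKBIA, ATF3 and TNFAIP3 are among them.

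The arrays came from 1 slide and 1 scan, so a slide or scan block could not be fitted. Untreated arrays lay in slide row 1 and DIMATE arrays in slide row 2, with the replicate number as the slide column.

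The tests were tested on simulated data. With independent noise of each gene's own spread, the DIMATE against untreated fit over 17499 genes recovered 46% of 50 genes changed 2-fold, 84% of 50 changed 4-fold and 96% of 50 changed 8-fold, and called 7 unchanged genes. With known changes added to the deposited DIMATE arrays, it recovered 0% of 200 genes at 1.5-fold, 18% at 2-fold, 88.5% at 4-fold and 98% at 8-fold, and called 0 unchanged genes at 2-fold and 2 at 4-fold and at 8-fold. The share at 2-fold depended on which genes were drawn and in which direction they were changed: 20 further draws of 200 genes gave 23.5% to 47%, with a median of 36%. In the simulated arrays the list raised by 0.5 log2 units, proteasome subunits, was called, and 0 others were. The simulated noise was independent between genes, while the correlation estimated for that list on the deposited arrays was 0.37. The simulation therefore does not measure how the list test performs on the deposited arrays.

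Alternatives covered background correction (normexp with an offset of 50), quantile, median or no scaling, the filter on dim probes, the mean of a gene's probes, outlier flags, the variance model, array weights, the replicate number as a block, leaving out each array, a test against a 1.2-fold change, and, added after seeing the data, 1 to 3 principal components of the deviations from the labelled group means as covariates.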

Results

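Gene expression was measured in HL60 cells, a human promyelocytic leukaemia line, on 8 one-colour arrays. Arrays of 4 samples labelled untreated were set against arrays of 4 samples labelled as given 10 µM DIMATE for 6 h. The series title names DIMATE as an inhibitor of ALDH1, and the design asks how HL60 expression after the compound compares with that of untreated cells. Between 50.7% and 53.5% of the spots on an array were well above background, and the 75th percentile of the signal lay between 284 and 495 intensity units. After filtering, 17499 genes and unnamed transcripts were tested, of which 12367 were protein-coding genes. All levels below are log2 signal minus the array's 75th percentile, differences are DIMATE minus untreated, and ± gives the SD over n = 4 arrays. The number of arrays limits the precision of each value. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

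Between the arrays labelled DIMATE and those labelled untreated, 0 genes differed past an adjusted p of 0.05 in limma, 0 higher and 0 lower, and 0 of 35 gene lists shifted. HMOX1, the haem oxygenase induced by electrophiles, was at 4.03 ± 0.15 in untreated and 3.99 ± 0.29 in DIMATE arrays. HLA-B, a heavy chain of MHC class I, was at 7.83 ± 0.21 and 7.85 ± 0.23. ALDH2, the mitochondrial aldehyde dehydrogenase, was at -3.21 ± 0.18 and -3.13 ± 0.22. Stress genes such as EGR1, HSPA6 and ATF3 varied by more than 8-fold between arrays of the same label, and their group means lay within 0.06 of each other.

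The smallest adjusted p in limma was 0.999894, and every gene named below has that same adjusted p. At an unadjusted p under 0.05 there were 239 genes, 62 higher and 177 lower in DIMATE, where chance alone would give 875. The median log2 difference over all tested genes was -0.0066. The 95% interval of the difference lay within 2-fold in either direction for 15981 genes, 91.3% of those tested. The values of the 4 arrays of one label lay wholly above those of the other label for 65 genes, against 500 expected by chance (2.86%).

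NRF2 targets answer electrophiles and oxidants. Of their 33 tested members 0 passed the test, with 16 point estimates above and 17 below 0. HMOX1, measured by a probe at chromosome 22, 35790122 to 35790181 of hg19, had a difference of -0.04 (95% interval -0.43 to 0.34). SRXN1, which encodes sulfiredoxin, was at 2.99 ± 0.09 and 2.99 ± 0.03, with an interval from -0.25 to 0.26. GCLM, the modifier subunit of glutathione synthesis, was at 3.07 ± 0.33 and 2.86 ± 0.22. NQO1, the quinone reductase, was at -1.78 ± 0.64 and -1.80 ± 0.70. TXNRD1, thioredoxin reductase, was at 0.36 ± 0.32 and 0.34 ± 0.40. OSGIN1 was at -1.21 ± 0.60 and -1.43 ± 0.66. SLC7A11, the cystine transporter subunit, was at 1.92 ± 1.07 and 1.93 ± 1.08, so that its interval ran from -1.41 to 1.44. For the NRF2 list the camera adjusted p was 0.905, and the adjusted p was 0.990 with an estimated correlation.

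Of 28 tested heat shock genes 0 passed the test, and 4 of them, HSPA6, HSPA1B, DNAJB1 and BAG3, had a within-group SD above 1. The median within-group SD of the list was 0.27, above that of 75.2% of random lists. HSPA6, an HSP70 that is induced by stress, was at 0.54 ± 2.91 and 0.50 ± 2.82. HSPA1B had a difference of -0.12 with an interval from -1.80 to 1.56. The HSP40 gene DNAJB1 was at 2.63 ± 1.13 and 2.56 ± 1.19, and the HSP70 cochaperone BAG3 at -2.68 ± 1.37 and -2.78 ± 1.51. HSPH1 varied less, at 5.15 ± 0.31 and 5.09 ± 0.30. The probe of HSPA1A was not well above background on any array. The camera adjusted p of the list was 0.905.

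The ATF4 list, which covers amino acid synthesis and the integrated stress response, had 0 of 44 members past the test and 6 with a within-group SD above 1. ATF3, a stress-induced transcription factor, was at 3.08 ± 1.77 and 3.10 ± 1.83. CHAC1, which degrades glutathione, was at 0.37 ± 1.47 and 0.28 ± 1.42 in untreated and DIMATE arrays. DDIT3, which encodes CHOP, had a difference of -0.08 with an interval from -1.36 to 1.19. TRIB3 was at 6.10 ± 0.56 and 6.08 ± 0.63. ASNS, asparagine synthetase, was at 4.85 ± 0.24 and 4.82 ± 0.30. The adjusted p of the ATF4 list was 0.971 in camera and 0.0216, higher in DIMATE, once DIMATE replicate 4 was left out, and the other alternatives gave 0.191 to 0.999596. The 0.0216 rests on camera's preset correlation of 0.01, while the correlation estimated for this list over all 8 arrays was 0.25.

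Genes of the unfolded protein response of the endoplasmic reticulum differed little between arrays. Of 33 tested members 0 passed the test, and 0 had a within-group SD above 1. HSPA5, the chaperone BiP, was at 2.42 ± 0.17 and 2.43 ± 0.22, and DNAJB9 at 1.79 ± 0.14 and 1.81 ± 0.05. HERPUD1 was at 4.56 ± 0.28 and 4.62 ± 0.35. Genes linked to immunogenic cell death had 0 of 21 tested members past the test. CALR, which encodes calreticulin, was at 8.70 ± 0.08 and 8.65 ± 0.11 (95% interval of the difference -0.31 to 0.23). HMGB1 was at 6.25 ± 0.19 and 6.22 ± 0.27, and ANXA1 at 5.15 ± 0.31 and 5.25 ± 0.27. Transcript levels say nothing of where these proteins lay in the cell.

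Genes of MHC class I presentation had 0 of 22 tested members past the test, 11 with an estimate above and 11 below 0. The probe named HLA-C was at 8.47 ± 0.18 and 8.43 ± 0.29. Its printed position, chromosome 6, 31321644 to 31321703 of hg19, overlaps that of the HLA-B probe, 31321653 to 31321712. It may therefore not measure HLA-C apart from HLA-B. B2M, the light chain of MHC class I, was at 8.11 ± 0.14 and 8.21 ± 0.11, and the peptide transporter gene TAP1 at 3.09 ± 0.28 and 3.11 ± 0.30. Among MHC class II genes 0 of 10 tested members passed. HLA-DOB was at -3.76 ± 0.27 and -3.32 ± 0.28, a difference of 0.44 (95% interval 0.01 to 0.88) at an unadjusted p of 0.047 in limma. Ligands of NK and T cell receptors had 0 of 25 tested members past the test. MICA, a ligand of NKG2D, was at 2.34 ± 0.28 and 2.37 ± 0.23, MICB at 1.93 ± 0.30 and 1.90 ± 0.23, and ULBP1 at -1.54 ± 1.06 and -1.42 ± 1.01. CD47, the signal against phagocytosis, was at 4.09 ± 0.20 and 4.20 ± 0.19. The 2 probes of CD274, which encodes PD-L1, were not well above background on any array. Interferon-stimulated genes had 0 of 27 tested members past the test, with ISG15 at 4.37 ± 0.29 and 4.32 ± 0.40 and IFIT1 at -2.94 ± 0.70 and -2.80 ± 0.66.

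Aldehyde dehydrogenase genes had 0 of 11 tested members past the test. ALDH1B1 was at 0.73 ± 0.25 and 0.70 ± 0.20, ALDH3B1 at 1.31 ± 0.64 and 1.46 ± 0.43, ALDH9A1 at 0.80 ± 0.29 and 0.90 ± 0.25, and ALDH18A1 at 1.37 ± 0.24 and 1.43 ± 0.27. ALDH1A1 was not tested, since neither of its 2 probes was well above background on more than 1 untreated or more than 2 DIMATE arrays. The probe of ALDH1A2 was not well above background on any array, and that of ALDH1A3 on 1 array. ALDH3A1 was left out because a probe spot was an outlier on an array.

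Genes of cell death and the cell cycle gave the same count. The p53 list had 0 of 27 and the apoptosis list 0 of 38 tested members past the test. CDKN1A, which encodes the cell cycle inhibitor p21, was at -1.24 ± 0.80 and -1.53 ± 0.86, and MDM2 at -1.05 ± 0.28 and -0.87 ± 0.22. The BH3-only genes BBC3 and PMAIP1 were at 1.55 ± 0.80 against 1.47 ± 0.83 and at 3.20 ± 0.62 against 3.14 ± 0.60. BCL2 was at 1.40 ± 0.41 and 1.47 ± 0.38, and MCL1 at 1.80 ± 0.95 and 1.93 ± 0.83. Of G1/S genes 0 of 38 and of G2/M genes 0 of 37 passed, with CCNE2 at 0.57 ± 1.14 and 0.55 ± 1.21, CCNB1 at 2.60 ± 0.50 and 2.63 ± 0.51, and PLK1 at 1.80 ± 0.70 and 1.56 ± 0.64. The replication gene CDC6 had a difference of -0.04 with an interval from -0.76 to 0.68. MYC was at 5.33 ± 0.40 and 5.39 ± 0.35. In the list of ferroptosis and iron handling 0 of 27 passed, with the transferrin receptor gene TFRC at 4.47 ± 0.51 and 4.54 ± 0.45 and the ferritin gene FTH1 at 7.77 ± 0.33 and 7.74 ± 0.28. In the list of promyelocyte granule proteins 0 of 18 passed, with myeloperoxidase, MPO, at 6.67 ± 0.30 and 6.59 ± 0.33 and AZU1 at 4.49 ± 0.55 and 4.28 ± 0.45.

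In all 35 lists the count of members past the threshold was 0, and adjusted over the list alone it was also 0 in each. Epithelial and fibroblast markers had the smallest set p, an unadjusted 0.0257 in camera over 7 members, and the adjusted p was 0.899. With an estimated correlation the adjusted p was 0.990 for each list, and fry gave 0.994. Markers of T and NK cells, B cells and erythroid cells had 0 of 12, 0 of 8 and 0 of 9 tested members past the test.

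**Figure D1:**
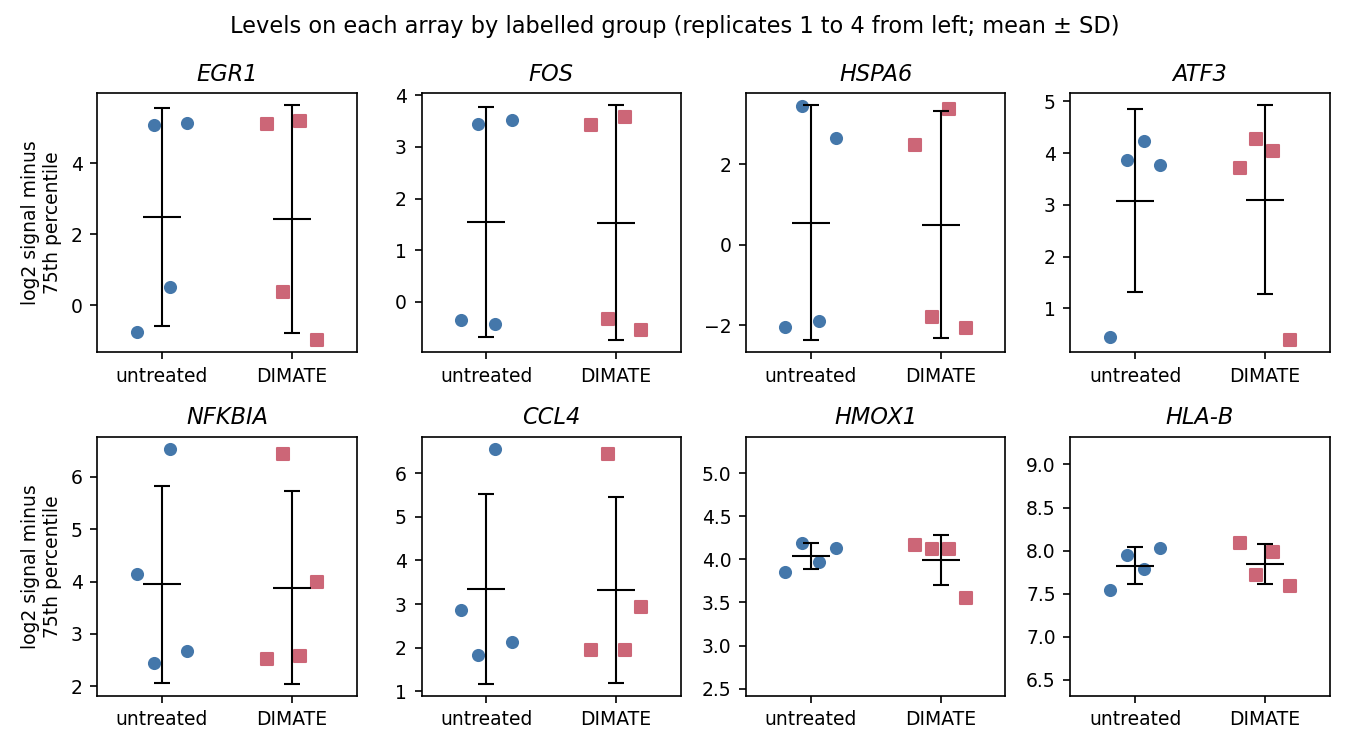
Level of 8 genes on each array, by labelled group. The vertical axis is log2 signal minus the array's 75th percentile, points are arrays in the order of replicates 1 to 4, and the bar with whiskers is the mean ± SD (n = 4). EGR1 lay at 5.06 and 5.14 on 2 untreated arrays and at -0.76 and 0.51 on the other two, and HMOX1 between 3.56 and 4.19 on all 8.

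A within-group SD above 1 was found for 238 genes. A range of at least 2 log2 units was seen for 416 genes in untreated and 286 in DIMATE arrays, 198 of them in both. EGR1, an immediate early transcription factor measured at chromosome 5, 137804891 to 137804950 of hg19, was at -0.76, 5.06, 0.51 and 5.14 on untreated arrays 1 to 4 and at 5.11, 0.39, 5.20 and -0.99 on DIMATE arrays 1 to 4. FOS was at -0.35, 3.45, -0.43 and 3.52 and at 3.43, -0.33, 3.58 and -0.55, and FOSB and DUSP1 had within-group SDs of 2.48 and 2.12 in untreated arrays. HSPA6 was at -2.04, 3.45, -1.89 and 2.65 and at 2.46, -1.79, 3.37 and -2.05. CD86, a costimulatory ligand of T cells, was at -0.25, 2.70, -0.09 and 3.80 and at 3.25, -0.36, 3.66 and 0.03. NFKBIA, the NF-kB inhibitor induced by NF-kB itself, was at 4.14, 2.45, 6.53 and 2.67 and at 2.52, 6.44, 2.58 and 3.99. The chemokine CCL4 was at 2.87, 1.84, 6.57 and 2.13 and at 1.95, 6.44, 1.95 and 2.92. ATF3 was at 0.45, 3.87, 4.23 and 3.78 and at 3.70, 4.28, 4.03 and 0.38. TNFAIP3 and BIRC3, further NF-kB targets, were highest on untreated array 3 (2.10 and 3.54) and on DIMATE array 2 (1.77 and 3.48). TNF was at 4.73 ± 0.91 and 4.61 ± 0.87, and IL1B at 3.51 ± 1.09 and 3.57 ± 1.02.

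**Figure D2:**
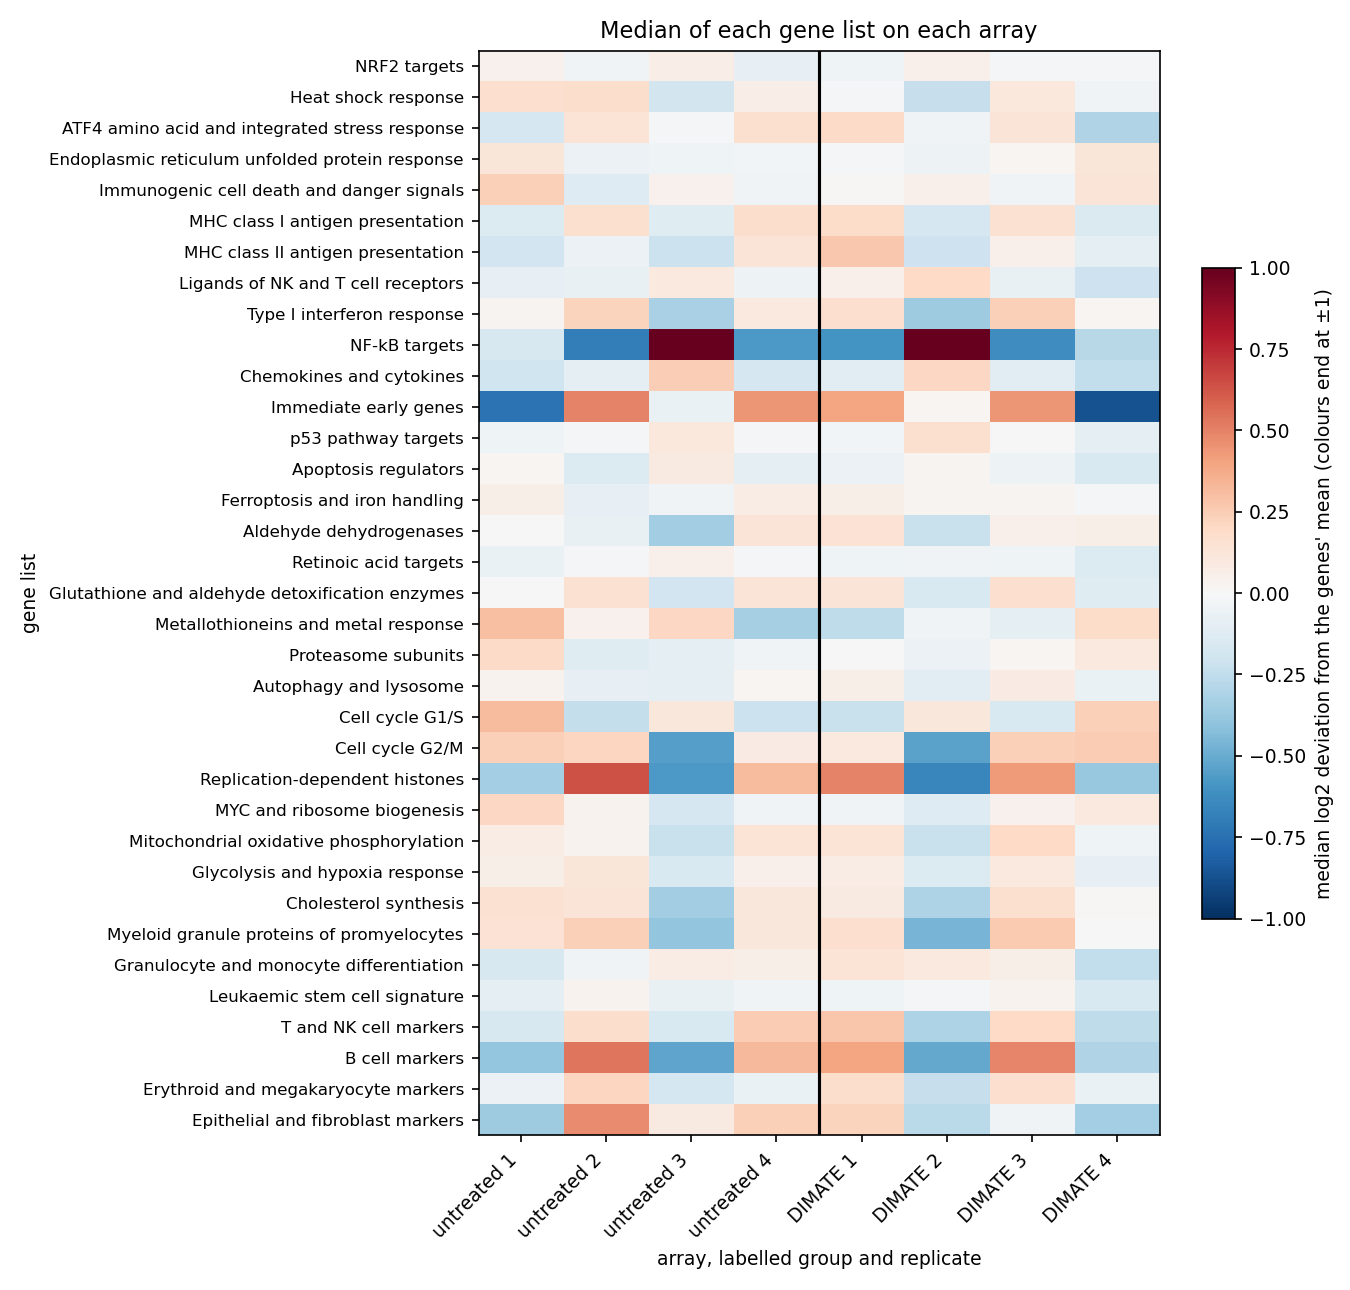
Median of each of the 35 gene lists on each of the 8 arrays. Rows are lists, columns are arrays with the 2 labelled groups parted by a line, and colour is the median log2 deviation of the members from their own mean over the 8 arrays. The NF-kB list lies outside the colour range on untreated replicate 3 (1.53) and DIMATE replicate 2 (1.48).

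By list, the median within-group SD exceeded that of 95% of 10000 random lists of the same size and mean level for 13 lists. For NF-kB targets it was 1.05, for immediate early genes 0.78, for chemokines and cytokines 0.60, for replication-dependent histones 0.59 and for G2/M genes 0.39. The median deviation of NF-kB targets was -0.16, -0.70, 1.53 and -0.57 on untreated arrays 1 to 4 and -0.60, 1.48, -0.62 and -0.28 on DIMATE arrays 1 to 4. Immediate early genes stood at -0.74, 0.50, -0.06 and 0.44 and at 0.39, 0.02, 0.44 and -0.87. Histone genes stood at -0.34, 0.64, -0.57 and 0.32 and at 0.50, -0.65, 0.43 and -0.38. G2/M genes stood at 0.24, 0.21, -0.55 and 0.09 and at 0.10, -0.54, 0.24 and 0.25. Leaving out 1 array made the labelled groups unequal in these genes, and some lists then passed the camera test. Without DIMATE replicate 2 the NF-kB list was lower in DIMATE (median -0.52), and without untreated replicate 3 it was higher (median 0.51). The camera test used its preset correlation of 0.01, while the estimate for NF-kB targets was 0.62.

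**Figure D3:**
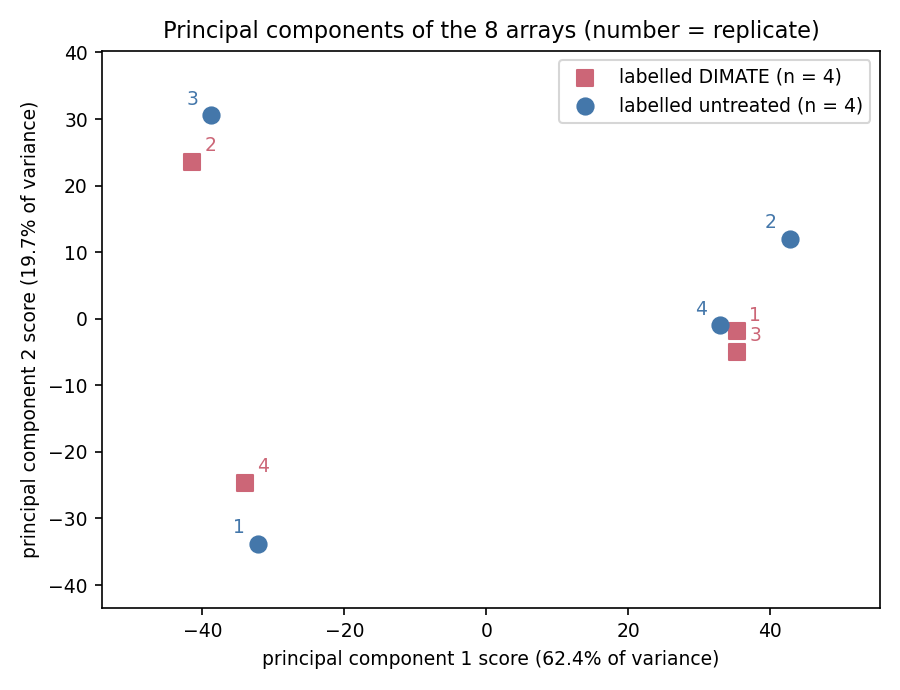
Principal components of the 8 arrays over all tested genes. The axes are the scores on the first component (62.4% of the variance) and on the second (19.7%), points are arrays, and symbols give the label. On each side of the first component lie 2 arrays labelled untreated and 2 labelled DIMATE.

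The labels did not separate the arrays. The first principal component held 62.4% of the variance, with scores of -32.1, 42.8, -38.7 and 32.9 for untreated arrays 1 to 4 and 35.3, -41.4, 35.3 and -34.0 for DIMATE arrays 1 to 4. For 7 of the 8 arrays the most similar array carried the other label. The correlation across genes, which are not independent replicates, was 0.996 between untreated replicate 1 and DIMATE replicate 4, 0.996 between untreated replicate 3 and DIMATE replicate 2, and 0.997 between untreated replicate 4 and DIMATE replicate 1. Within a label it ranged from 0.977 to 0.997. The 75th percentile of the signal was 495, 284, 385 and 369 on untreated arrays 1 to 4 and 300, 414, 348 and 449 on DIMATE arrays 1 to 4, so that each array with a negative score was brighter than each with a positive score. Between labels it stood at 384 ± 86.6 and 378 ± 66.7 intensity units (two-sided exact permutation p = 0.886 over 70 arrangements, adjusted p = 0.914 over 3 measures). The share of spots well above background gave an exact permutation p of 0.914. The median log2 signal of the spike-in controls was 11.98 ± 0.06 in untreated and 11.81 ± 0.11 in DIMATE arrays (two-sided exact permutation p = 0.0571, adjusted p = 0.171).

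Among genes with an unadjusted p under 0.05, POR, the reductase that supplies electrons to cytochrome P450 enzymes, was at 7.72 ± 0.37 and 6.69 ± 0.54, a difference of -1.03 (95% interval -1.68 to -0.38; chromosome 7, 75544784 to 75544843 of hg19). POR was at 7.91, 8.14, 7.34 and 7.47 on untreated arrays and at 7.50, 6.39, 6.41 and 6.45 on DIMATE arrays, so that DIMATE replicate 1 lay among the untreated arrays. The mean over the tested probes of POR, the chosen probe included, gave -0.54. DIABLO, a mitochondrial protein released in apoptosis, was at 8.55 ± 0.21 and 7.97 ± 0.49, a difference of -0.58, and its probe mean gave -0.31. For both genes the other tested probes thus fell less on average than the chosen probe. All untreated arrays lay in one row of the slide and all DIMATE arrays in the other, so that slide row and label cannot be told apart.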

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

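Arrays standing apart from the other 3 of their label were sought with Dixon's ratio. It is the gap to the nearest array over the range of the group. Of 210 groups of 4 values, 17 passed the 95% critical value, where chance alone passes about 1 group in 20. Among array measures 2 of 6 passed, and among list medians 4 of 70, near the 3.5 that chance gives. Among the 67 named genes 11 of 134 groups passed. These genes were settled on after their values were seen, so the chance rate does not hold for them. The tests of the pattern weighed here were chosen after the result was seen.

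In the share of spots well above background, untreated replicate 1 stood apart at 53.5% (ratio 0.932) and DIMATE replicate 1 at 50.7% (ratio 0.885). Untreated replicate 3 stood apart for TNFAIP3 (level 2.10, ratio 0.957), SLC7A11 (3.50, ratio 0.847), FTH1 (8.26, ratio 0.907), HSPA5 (2.16, ratio 0.908) and CCNB1 (1.86, ratio 0.860), and for the medians of p53 targets (0.11, ratio 0.853) and cholesterol synthesis genes (-0.34, ratio 0.920). DIMATE replicate 2 stood apart for TNFAIP3 (1.77, ratio 0.986), CALR (8.49, ratio 0.904) and the median of NF-kB targets (1.48, ratio 0.838). ATF3 was far lower on untreated replicate 1 (0.45, ratio 0.880) and on DIMATE replicate 4 (0.38, ratio 0.853) than on the other arrays of each label. DIMATE replicate 4 also had the lowest HMOX1 (3.56, ratio 0.915) and the lowest median of retinoic acid targets (-0.14, ratio 0.984).

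POR stood apart on DIMATE replicate 1 (7.50, ratio 0.940), and the same order of arrays recurred in the 177 genes that were lower in DIMATE at an unadjusted p under 0.05. In 83.6% of them DIMATE replicate 1 lay above the other 3 DIMATE arrays, against 28.2% of all other genes and 25% by chance. In 77.4% of them both untreated arrays of slide columns 1 and 2 lay above both of columns 3 and 4, against 9.35% of the other genes and 16.7% by chance. These genes thus share an order of arrays where none was labelled treated. The other genes were not picked by p and so are not a matched comparison, and the 62 higher genes were not counted in this way. Each column held 1 untreated array, so slide column cannot be told from a difference between samples. These 177 genes are fewer than chance would give in one direction. The imbalance against 62 higher genes varied with the setting. At an unadjusted p, 313 of 656 genes were higher without a filter, 281 of 623 with array weights and 102 of 202 without DIMATE replicate 4. It was stronger in other settings, such as 10 of 167 higher with normexp background and 24 of 155 with the replicate block. A gradient over slide positions is a candidate explanation of the shared order of arrays in these genes, and a weak effect of DIMATE on them cannot be told apart from it, since slide row and label coincide.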

How the results depend on the processing

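The count of genes past the adjusted threshold, in either direction and at 2-fold, was 0 in the chosen setting and in each of the 23 other settings that give one; the count at an unadjusted p under 0.05 ranged from 155 (replicate block) to 1261 (3 covariates), leaving aside 82 in the test against 1.2-fold. The smallest adjusted p of a setting ranged from 0.274, with array weights, to 0.999999. The covariate settings were added after seeing the data. The median difference of all genes stayed between -0.033 and 0.029. Direction was compared only where a value passed the threshold; point estimates near 0 changed sign for up to 28 of the 67 named genes and up to 18 of the lists. With all 8 arrays 0 lists shifted in any setting. Leaving out 1 array gave 0 to 8 shifted lists: 2 without untreated replicate 1, 1 without replicate 2, 4 without replicate 3 and 1 without replicate 4, and 0, 4, 0 and 8 without DIMATE replicates 1 to 4. These calls rest on camera's preset correlation of 0.01: at that setting 28 of the 35 splits of the arrays called at least 1 list, and the correlation estimated from the data was 0.25 for the ATF4 list, 0.62 for NF-kB targets, 0.74 for G2/M genes and 0.86 for histones. Over these omissions the list medians ranged from -0.52 to 0.51 for NF-kB targets, -0.16 to 0.17 for G2/M genes and -0.074 to 0.096 for G1/S genes, and these 3 lists were called in both directions. Of 20 list calls in these omissions, 4 ran against the direction in the chosen setting. Histones were called higher in all 3 omissions that called them (untreated replicate 2, DIMATE replicates 2 and 4), and metallothioneins lower in both of theirs (untreated replicate 4, DIMATE replicate 4). Each omission makes the groups unequal in size and in their mix of array profiles; beyond that the cause was not tested. With the replicate number as a block 0 genes and 0 lists were called. Deviations of same-numbered arrays correlated at -0.711 to -0.528, and for every number these arrays lay on opposite sides of the first component. Whether the numbers pair the samples cannot be told from that. A slide or scan block was not run, since there was 1 of each. With the mean of a gene's probes, POR had -0.54. Signal too close to background kept ALDH1A1, ALDH1A2, ALDH1A3, CD274 and HSPA1A out of the chosen setting.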

Other observations

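The tests of the 3 explanations in the last paragraph were chosen after the result was seen, and the splits were read after it too. B cell markers and granule protein genes of promyelocytes had a median within-group SD above that of 99% of random lists. B cell markers, 8 of which were tested, had medians of -0.39, 0.54, -0.53 and 0.33 on untreated arrays 1 to 4 and 0.40, -0.51, 0.49 and -0.30 on DIMATE arrays 1 to 4. Granule protein genes stood at 0.14, 0.24, -0.40 and 0.11 and at 0.17, -0.46, 0.26 and 0.00. Proteasome and autophagy genes were among the steadiest, with a median within-group SD of 0.16 and 0.17, below 99% of random lists. In limma, members past the threshold numbered 0 of 12 retinoic acid targets, 0 of 26 detoxification enzymes, 0 of 11 metallothioneins, 0 of 34 proteasome, 0 of 31 autophagy, 0 of 20 histone, 0 of 42 MYC, 0 of 40 oxidative phosphorylation, 0 of 32 glycolysis, 0 of 24 cholesterol, 0 of 30 differentiation and 0 of 11 stem cell genes, 0 of 26 NF-kB targets, 0 of 26 chemokines and 0 of 33 immediate early genes.

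The labelled split called 0 genes, 0 higher, 0 lower, 0 at 2-fold and 0 lists (limma, with 239 genes at an unadjusted p under 0.05, and camera). Each of the 35 splits of the 8 arrays into 4 and 4 gives at least as many by construction, so this count says nothing of chance. The highest values of another split were 8645 genes, 5476 in one direction, 1339 at 2-fold and, in a further split, 16 lists. The split with 8645 genes placed 2 arrays of each label on each side, and the next split called 1 gene. Such a count points to a structure of the samples that the labels do not describe.

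Why arrays of both labels share profiles was weighed with 3 explanations. Scaling between arrays is argued against as the source of the widest spreads, since quantile normalization left 219 genes with a within-group SD above 1, of 238 before. Normexp background left 94, so background treatment bears on that count. The first component and the most similar arrays were not recomputed after either change, so these counts do not decide whether brightness or signal processing gave the shared profiles. Brightness did run with the first component, yet the 75th percentiles of 284 to 495 units span less than 2-fold, while EGR1 ranged from -0.76 to 5.14 log2 units on untreated arrays. Whether the samples themselves made some arrays brighter was not tested. The next explanation was a difference between cultures or handling that widened the spread and so hid 2-fold effects of DIMATE on many genes. Over the tested genes as a whole it is argued against. With 1, 2 or 3 components of the deviations as covariates 0 genes were called (525, 969 and 1261 at an unadjusted p). The same fits recovered 71% to 92% of added 2-fold changes over 20 draws of 200 genes, against 23.5% to 47% without covariates. Those fits also called 6 to 14 genes that had not been altered. The draws came from all 17499 tested genes, and recovery was not counted apart for the 238 with a within-group SD above 1. Effects of 2-fold on those genes, such as HSPA6 and ATF3, therefore stay open. The unadjusted counts with 2 and 3 components exceeded the 875 expected by chance. Smaller changes were not tried with covariates, so weaker effects on many genes stay open. The components are uncorrelated with the label and leave the differences as they were, so a handling difference that offset an effect would not show. Labels that do not match the arrays remain a candidate explanation, as 8645 genes were called by a split that moves 2 arrays of each label, although an exchange of labels alone leaves untreated replicates 1 and 3 apart in NFKBIA (4.14 and 6.53) and ATF3 (0.45 and 4.23). A difference in culture or handling that ran through both groups alike, beside a compound with little effect at 6 h, would give the same counts and stays open, and which label any array should carry was not inferred.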
